A study of Mus musculus with 6 samples.

How the data were processed

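The series holds 6 arrays of 2 channels each, with RNA of sorted mouse endothelial cells after tobacco smoke in channel 1 and of control cells in channel 2, per the labels. The deposited value table gives 1 log2 ratio for each of 32448 features on each array. The labels and the file state no scanner, background correction, normalization, filter or dye for either channel, so these steps are unknown. From the values, the deposited columns are log2 of folds in whole hundredths, to within 0.02 of a hundredth, for 100% of the values on 5 arrays and 99.99% on 1-week replicate 2, and each has a median of 3e-07. The log base, the centring and the direction of the ratio are not stated. Intensities were not used here, so signal over background and dim spots were not assessed.

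A probe table paired 24344 features with 1 gene symbol and 98 with several, and 8006 features were absent from it. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, used for names only: 24076 features matched, 268 kept the symbol of the probe table and 0 symbols changed. No coordinates are given. The last 5550 features, after the last named one, had paired values with correlations near 0 and were kept as unnamed tests. Features with several symbols or none were tested on their own and not named. Log2 ratios of features with 1 symbol were averaged per array, giving 11138 named genes, 10180 of them with 2 spots and 958 with more. There were no missing values.

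Each array was centred on its median. Arrays without a dye-reversal label kept their sign, and a dye-reversed array was turned if its correlation over all genes with the unreversed arrays of its comparison was below 0. This turned the 6-week and not the 1-week dye reversal. The 2 arrays of 6-week smoke against 1-week control were averaged as a technical dye swap. The resulting 5 replicates were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a coefficient for each exposure time. Contrasts were 1-week, 6-week, 6-week minus 1-week and the mean of both times, two-sided, with Benjamini-Hochberg adjustment over 19242 tests and a threshold of 0.05. There were 3 residual degrees of freedom, and the estimated prior degrees of freedom were 2.42. Neither the control's age nor the dye was a term of this model; both entered alternatives.

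Before the data were examined, 32 lists of genes were fixed. They cover responses to smoke constituents and stress, endothelial function and inflammation, matrix, cell cycle and death, metabolism, ribosome and proteasome, clock and glucocorticoid genes, markers of other cell types, and sex-linked genes. The 31 lists with at least 5 measured genes were tested in 3 contrasts with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 93 tests. Camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone are given beside counts over all genes.

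Genes to name were fixed by rule. For each contrast these were up to 12 genes of each sign with the largest mean among those that passed with one sign on every array, filled up by the smallest p among genes with one sign on every array and a mean over 0.58 in size. Added were list members that passed, up to 4 members per list with the smallest p, Cyp1a1 and Cyp1b1, 10 genes of each sign with the largest smallest group mean over all comparisons, and 5 genes of each sign that differed most with the control's age. The text names part of this set. The same rule was also applied with all arrays signed as deposited. Adipoq, Retn, Edn1, Car4, Cd74, Tpt1 and Eef1a1 fall outside the rule and were chosen after their values were seen.

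Alternatives fixed beforehand changed the centring, scale, normalization between arrays, sign of the dye-reversed arrays, dye term, averaging of dye swaps, control age, summary of spots, filter, variance model, arrays in the fit, threshold and each array in turn. After seeing the data 4 were added: all arrays signed as deposited, the 4 arrays without dye reversal, genes whose paired spots differed by less than 1 log2 unit on all arrays (5790 genes), and the last together with signs as deposited.

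The code was tested on simulated data with 19242 features, normal noise with the moderated spread estimated for each real feature, and 1 array turned. The sign rule turned that array back. The simulated noise was independent between arrays and held no dye effect, so this does not show that the rule works on the real arrays. For the same reason, the shares of called genes given next need not hold on the real arrays. In the simulated 1-week comparison, 80% of 50 genes changed 4-fold and 4% of 50 genes changed 2-fold were called, with 4 unchanged genes called. In the simulated 6-week comparison, 0% of 50 genes changed 4-fold were called, while 98% had an unadjusted p under 0.05. In the simulated difference, 0% of 100 genes changed 4-fold were called, with 92% at an unadjusted p under 0.05. For the mean of both times, 0% of 100 genes changed 4-fold at 1 exposure time were called, with 96% at an unadjusted p under 0.05. With this number of arrays, calls over all features were thus reached only at 1 week in the simulation. A simulated list shifted at 1 week was called by camera, and 0 unshifted lists were. The simulated noise was also independent between genes, so this does not show how camera behaves when the genes of a list vary together.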

Results

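Gene expression was measured in endothelial cells sorted from mice exposed to tobacco smoke and from control mice, on 6 arrays that each compared 2 RNA samples. The tissue the cells came from was not stated. Exposure for 1 week was set against control on 3 arrays, 1 of them with the dyes reversed. Exposure for 6 weeks was set against 1-week control on 2 arrays with the dyes exchanged between them, and against 6-week control on 1 array. The 2 arrays with exchanged dyes were averaged as 1 replicate, so the 1-week comparison had 3 replicates and the 6-week comparison had 2. The 1-week dye reversal was counted as a separate replicate, although no label says whether it repeats the RNA of another 1-week array. The labels do not say whether the arrays of a comparison came from separate animals. The p-values given here therefore refer to arrays, and the number of arrays limits the precision. Except in stated alternatives, each SE and p-value uses 1 spread per gene, pooled over all 5 replicates and moderated across genes. That spread includes the difference between the 6-week replicates, which had different controls. The age of the 1-week comparison's control was not stated, and the arrays against 1-week control may have shared control RNA.

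Nothing in the files states which RNA is the numerator of the ratios. Every title names smoke first and channel 1 holds the smoke sample on all 6 arrays, including the dye-reversed ones, so a positive log2 ratio is read here as likely higher after smoke. Whether the ratios of the 2 dye-reversed arrays had been turned before deposit is also not stated. Under a rule fixed before the data were examined, the 1-week dye reversal kept its sign (r = 0.0589 across all genes tested with the unreversed 1-week arrays) and the 6-week dye reversal was turned (r = -0.0141 with its unreversed partner). Genes are not independent replicates, and both correlations are close to 0. Values with all 6 arrays signed as deposited are therefore given beside those of the rule for the main counts, for genes named beyond 1 week and for lists called under either sign. That alternative was chosen after seeing the data, as was the restriction to genes with agreeing spots, meaning that the paired spots of a gene differed by less than 1 log2 unit on every array.

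The arrays carried 11138 named genes, nearly all in paired spots, and 8104 unnamed features, for 19242 tests. Paired spots of named genes correlated between r = 0.212 and r = 0.412 within an array, and 5790 named genes had agreeing spots. Across named genes, which are not independent replicates, the unreversed 1-week arrays correlated at r = 0.148, and the 1-week dye reversal correlated with them at r = 0.0719 and r = 0.103. The 6-week array and its dye reversal correlated at r = -0.0302 as deposited, at r = 0.0398 among genes with agreeing spots and at r = 0.166 among genes whose spots differed by less than 0.5, so the sign of the correlation that decides the rule's turn changed on the better spots. The 2 dye-reversed arrays correlated with each other at r = 0.272, the highest value of all pairs across named genes. Among genes whose spots differed by less than 0.5 they correlated at r = 0.510, below the unreversed 1-week arrays at r = 0.557.

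**Figure D1:**
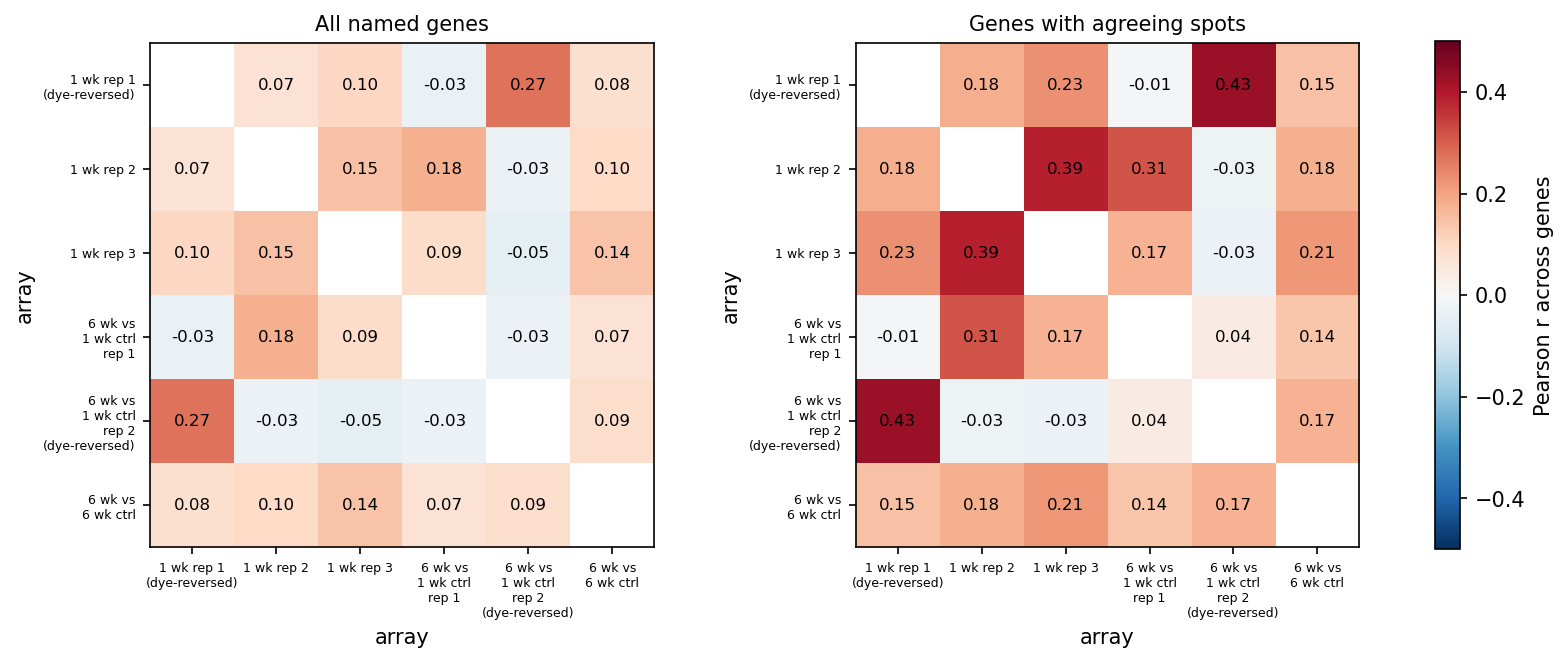
Pearson correlation across genes (colour and number) between each pair of the 6 arrays, with signs as deposited, for all named genes (left) and for genes with agreeing spots (right). The highest value in both panels belongs to the 2 dye-reversed arrays, at 0.272 and 0.430.

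After 1 week of smoke, ribosomal protein genes had negative log ratios as a group, while single genes of varied function stood out on both sides. Rps18 and Rplp2, which encode ribosomal proteins, had mean log2 ratios of -2.25 ± 0.16 and -2.12 ± 0.18 over 3 arrays (likely lower after smoke). The SE comes from the spread pooled over all replicates. Klf2, a transcription factor that endothelial cells induce under flow, stood at -1.34 ± 0.18, and Col4a2, a chain of basement membrane collagen, at -1.74 ± 0.23. Serinc1, a membrane protein that helps place serine into lipids, had a mean of 1.85 ± 0.22 (likely higher after smoke).

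This comparison asks how the endothelium responded to a short exposure. No gene passed limma's test with Benjamini-Hochberg adjustment over all 19242 tests: the count was 0, and the smallest adjusted p was 0.203. An unadjusted p under 0.05 was reached by 1215 features, 643 positive and 572 negative, where chance alone gives 962; leaving out each array in turn gave 853 (without 1-week replicate 3) to 1224. Robust limma and the test without variance moderation also gave 0. Among the 5790 genes with agreeing spots, 78 passed, 43 positive and 35 negative. This count takes the 1-week dye reversal as a separate replicate, and averaging it with another array was not tried among these genes. With all arrays signed as deposited, 102 of these genes passed (57 positive, 45 negative), and 76 of the 78 were among them. The rule left the 1-week dye reversal as deposited, so each gene's 1-week mean and direction were the same under both signs. Only the estimate of the spread differed. The genes named next did not pass over all tests. Those said to pass did so in a separate fit of genes with agreeing spots. The adjusted p-values under 0.05 given for single genes at 1 week come from that fit. Each 1-week mean ± SE comes from the fit over all tests, so the SE and the adjusted p-value of a gene belong to different fits.

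Among the positive genes that passed, Gpr160, an orphan receptor, had a mean log2 ratio of 1.57 ± 0.19, Mfsd8, a lysosomal membrane protein, 1.53 ± 0.18, and Hnrnpm, which binds pre-mRNA, 1.48 ± 0.21. Nbr1, a receptor for selective autophagy, stood at 1.17 ± 0.15, Rab5a, a GTPase of early endosomes, at 1.06 ± 0.15, and Sfr1, a recombination repair factor, at 1.11 ± 0.16. Serinc1, Gpr160 and Mfsd8 each had an adjusted p of 0.00897, Hnrnpm and Nbr1 one of 0.0138, and Rab5a and Sfr1 one of 0.0189. Ephx2, which hydrolyses epoxides of fatty acids, was at 1.69 ± 0.25, but its paired spots differed by up to 2.39 log2 units, so it was not in this test. Among the negative genes that passed, Dynll1, a dynein light chain, was at -2.01 ± 0.23, Ifi27l2a, an interferon-inducible gene, at -1.62 ± 0.23, Dpt, a matrix protein of fibroblasts, at -1.33 ± 0.18, Eif3k, a subunit of a translation initiation factor, at -1.30 ± 0.18, and Trmt112, a partner of methyltransferases that modify RNA and translation factors, at -1.20 ± 0.16. Rps18 had the smallest adjusted p of all, 0.00111, followed by Rplp2 with 0.0018. Klf2, Col4a2, Ifi27l2a, Dpt, Eif3k and Trmt112 each had an adjusted p of 0.0138. These sizes rest on the sign of the 1-week dye reversal: with the dye-reversed arrays given the other sign, Rps18 was at -0.67, Rplp2 at -0.83, Dynll1 at -0.34, Klf2 at -0.24, Col4a2 at -0.55, Serinc1 at 0.61, Gpr160 at 0.73 and Mfsd8 at 0.58.

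The cytosolic ribosomal protein genes lay below other genes as a group at 1 week. Of 62 measured genes, 50 had a negative and 12 a positive log ratio, with a median of -0.39, and the medians of the 3 arrays were -0.37, -0.40 and -0.43. Adjusted over the list alone, 15 genes passed, against 0 over all genes tested. Rps16 was at -1.58 ± 0.26 and Rps24 at -1.53 ± 0.24, both passing among genes with agreeing spots. Limma's camera test placed the list below other genes with an adjusted p of 5.48e-13 under its preset inter-gene correlation. With an estimated correlation the adjusted p was 0.854. Fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.0737, and 0.000277 with signs as deposited. The camera call was lost with the dye-reversed arrays given the other sign, where the median was -0.14 and the adjusted p 0.189. All 3 arrays had a negative median, so a smaller median follows from turning 1 of them. No list passed in any contrast with an estimated correlation, so every camera call given here rests on the preset value.

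Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, had a median of -0.22 over 48 measured genes, with 31 negative and 17 positive. Camera's adjusted p was 0.0311, against an adjusted p of 0.934 with an estimated correlation, and 5 genes passed when adjusted over the list alone. The call rested on single arrays, since camera's adjusted p was 0.265 without 1-week replicate 1 and 0.0729 without the 6-week array against 1-week control; the median was -0.13 without 1-week replicate 3, and -0.04 with an adjusted p of 0.989 with the dye-reversed arrays given the other sign. Ndufb7, a subunit of complex I, was at -1.03 ± 0.16, Ndufs7, another, at -0.95 ± 0.19 and Ndufb5 at -0.77 ± 0.15, while Uqcrfs1, the iron-sulfur subunit of complex III, was positive at 0.84 ± 0.16. The proteasome list had a median of -0.20 over 29 genes, 21 of them negative, with a camera adjusted p of 0.052, above the threshold, and an estimated-correlation adjusted p of 0.934. With signs as deposited these were 0.0313 and 0.674. Psmd6, a subunit of the proteasome's regulatory particle, was at -0.99 ± 0.17. The proteasome median became -0.13 without 1-week replicate 1 and 0.05 with the dye-reversed arrays given the other sign.

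Within the other lists, single genes stood out while the lists as a whole did not pass. Of the extracellular matrix and basement membrane genes, 13 were positive and 14 negative, with 4 passing when adjusted over the list alone. Besides Col4a2, the companion chain Col4a1 was also negative, with paired spots that differed by up to 1.46, Sparcl1, a matrix-associated glycoprotein, at -1.09 ± 0.24, and Lamc1, a laminin chain, at -0.71 ± 0.17. Of the p53 and apoptosis genes, 14 were positive and 7 negative, with 3 passing when adjusted over the list alone. Trp53inp1, a p53-induced stress protein, was at 1.19 ± 0.19 and Btg1, which restrains proliferation, at 1.27 ± 0.21, whereas Cdkn1a, the cell cycle inhibitor p21, was at -0.68 ± 0.16. Tsc22d3, a glucocorticoid-induced leucine zipper protein, was at 1.28 ± 0.26, and 3 of the 12 glucocorticoid-induced genes passed when adjusted over the list alone, with opposite signs: Tsc22d3 was positive, and Cdkn1a and Mt2 (-1.30) were negative. Calcrl, a receptor for the vasodilator adrenomedullin, was at 1.15 ± 0.25, Cav1, the coat protein of caveolae, at 0.67 ± 0.17, and Hif1a, the oxygen-regulated transcription factor, at 0.91 ± 0.22. Ccn1, a matricellular protein, was at 0.99 ± 0.19 and Klf4, a transcription factor of quiescent endothelium, at 0.83 ± 0.25, while Jund was at -0.64 ± 0.16. Fabp5, a fatty acid carrier of endothelial cells, stood at -1.27 ± 0.24. With the dye-reversed arrays given the other sign, Sparcl1 and Lamc1 were each at -0.09, Fabp5 at -0.20, Cav1 at 0.12 and Btg1 at 0.25. Trp53inp1 shrank less, to 0.62.

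Genes classically induced by smoke constituents showed no shared positive change at 1 week. Of the aryl hydrocarbon receptor targets, 4 of 9 were positive, with a median of -0.01. Cyp1a1, which oxidises polycyclic hydrocarbons, had a mean of -0.01 ± 0.17, and Cyp1b1, its relative in vessels, 0.59 ± 0.30, which became 0.24 without 1-week replicate 1 and -0.28 with the dye-reversed arrays given the other sign. Of the NRF2 and glutathione genes, 13 of 31 were positive, with a median of -0.07. Hmox1, which breaks down heme, was at -0.67 ± 0.25 (-0.41 without 1-week replicate 2) and Gstm1, a glutathione transferase, at -0.70 ± 0.18. Mt2, a metal-binding stress protein, was at -1.30 ± 0.22 and Gpx1, which reduces peroxides, at -0.70 ± 0.19, within an antioxidant list that had a median of -0.06 over 13 genes. The endothelial activation and NF-kB genes had a median of -0.07, with 17 of 22 negative, and Ccl2, which attracts monocytes, was at -0.87 ± 0.24. With the dye-reversed arrays given the other sign, Ccl2 became 0.10 and Gpx1 became 0.01.

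**Figure D2:**
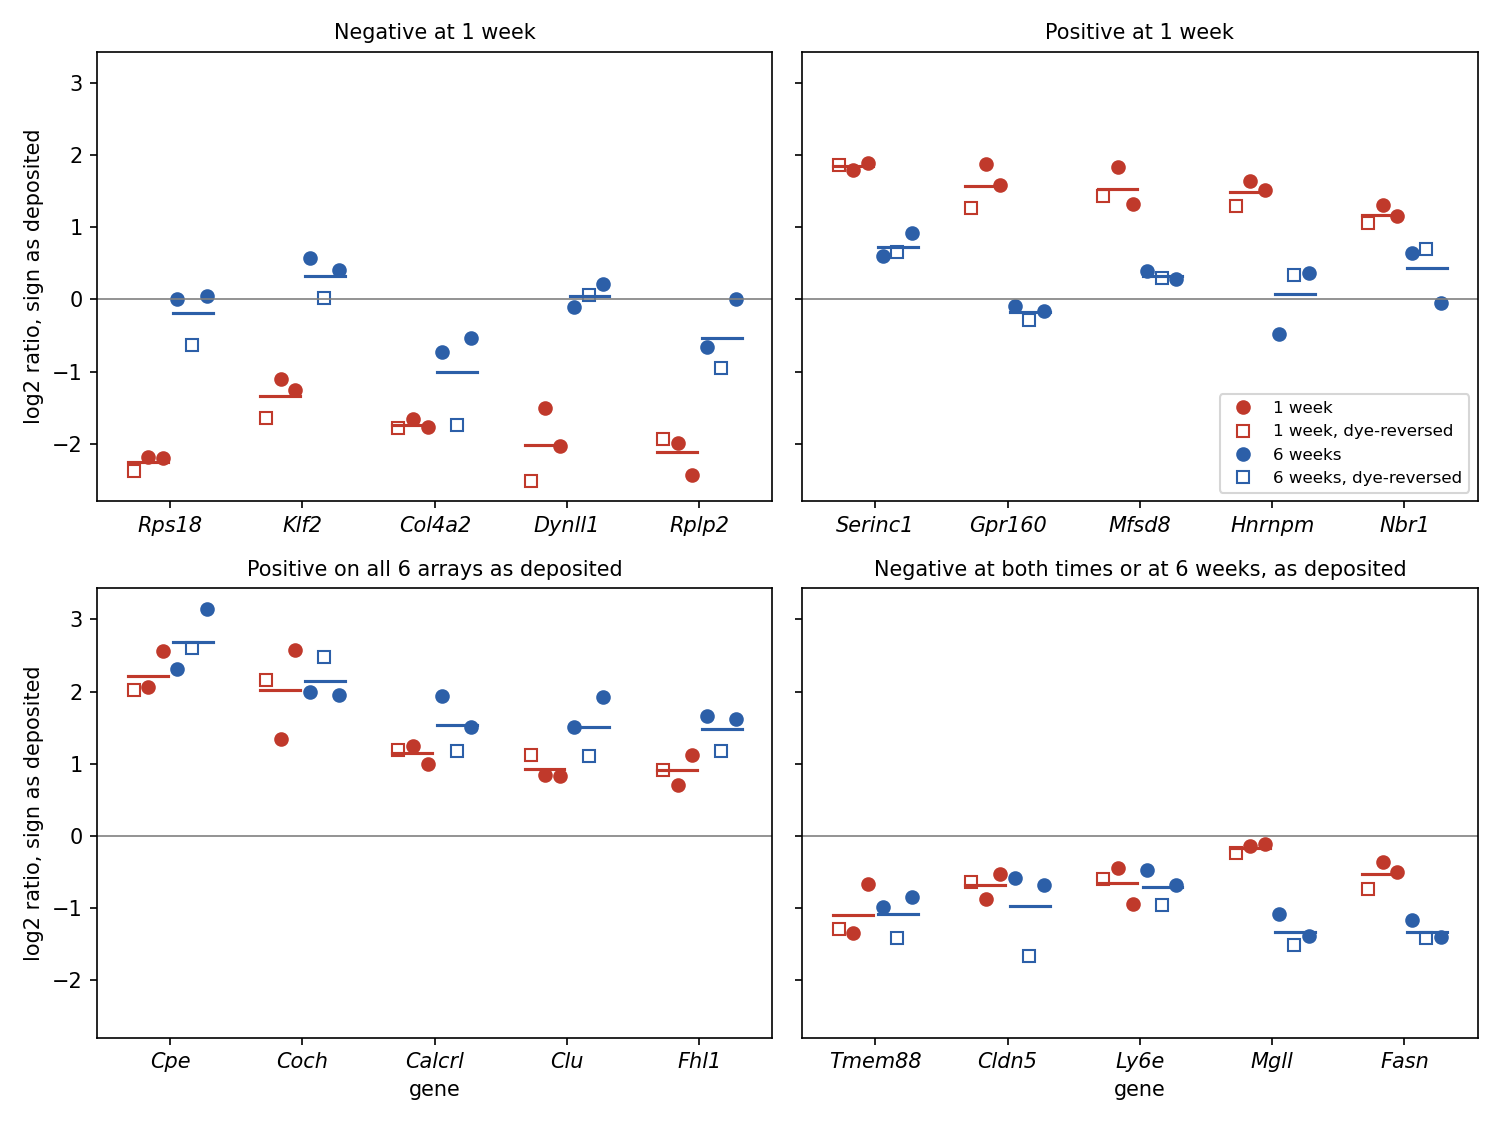
Log2 ratio (vertical axis, sign as deposited) of 20 genes on each of the 6 arrays: red for 1 week, blue for 6 weeks, open squares for dye-reversed arrays, with a bar at the mean of the 3 arrays of each exposure time. Rps18 lies between -2.38 and -2.18 on the 1-week arrays and between -0.63 and 0.05 on the 6-week arrays, and Cpe lies between 2.02 and 3.15 on all arrays.

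After 6 weeks of smoke the picture depended on the sign of the dye-reversed array. With all arrays signed as deposited, 12 genes passed among those with agreeing spots, 10 positive and 2 negative. Plagl1, an imprinted zinc finger transcription factor, had a mean log2 ratio of 2.20 ± 0.19 over 2 replicates (SE from the pooled spread, likely higher after smoke). The SEs given as deposited for the genes that passed come from the fit of genes with agreeing spots. Serpina1c, a serum protease inhibitor, was at 2.09 ± 0.19 and Clu, a secreted chaperone, at 1.62 ± 0.21. Mgll, which breaks down monoglycerides, was at -1.34 ± 0.17 and Fasn, the fatty acid synthase, at -1.34 ± 0.18 (likely lower after smoke). With the 6-week dye reversal turned, these means shrank to 1.05 for Plagl1, 1.01 for Serpina1c, 1.06 for Clu, -0.58 for Mgll and -0.64 for Fasn, and none of the 5 passed.

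This comparison asks what a longer exposure did. With the rule's sign, limma gave 0 passing genes over all tests, with a smallest adjusted p of 1. An unadjusted p under 0.05 was reached by 589 features where chance gives 962, and leaving out each array in turn moved this to between 525 and 1059 (the latter without the array against 6-week control). Robust limma also gave 0, and the test without moderation gave 3. Signed as deposited, the count was again 0, with 792 features at an unadjusted p under 0.05. Among genes with agreeing spots, 0 passed with the rule's sign and 12 passed as deposited, 10 positive and 2 negative. The 12 comprised Plagl1, Serpina1c, Clu, Calcrl, Ecrg4, Fhl1, Ahsg, Aspn, Coch, Spi1-6, Mgll and Fasn, with adjusted p from 0.00721 to 0.0251. Means as deposited were 1.53 ± 0.18 for Calcrl, 1.56 ± 0.19 for Ecrg4, a secreted peptide precursor, 1.52 ± 0.19 for Fhl1, a LIM domain protein of muscle and vessels, 1.53 ± 0.19 for Ahsg, the serum protein fetuin-A, and 1.72 ± 0.23 for Aspn, a small matrix proteoglycan. With the rule's sign these means were 0.94 for Calcrl, 0.78 for Ecrg4, 0.93 for Fhl1, 0.53 for Ahsg and 1.04 for Aspn. The 6-week replicates had different controls, which limits what their mean can show.

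With the rule's sign, the genes with one sign on every array and the smallest p had paired spots that often disagreed, and none passed. By this choice their deposited values had opposite signs on the 2 arrays with exchanged dyes, as Rgcc did at -1.23 and 2.14. A gene-specific dye effect would also give this if the dye-reversed ratio was turned before deposit, and the choice does not separate the 2. Rgcc, a regulator of the cell cycle and of complement responses, was at -1.86 ± 0.26, Rnf112, a ring finger protein, at -1.48 ± 0.27, Rps6, a ribosomal protein, at -1.01 ± 0.21, Selenon, a selenoprotein of the endoplasmic reticulum, at -0.95 ± 0.20, Dgcr8, which processes microRNA precursors, at -0.94 ± 0.22 and Csnk1d, a clock-associated kinase, at -0.93 ± 0.23. Lrrc71 was at 1.48 ± 0.24, Tsfm, a mitochondrial translation factor, at 1.38 ± 0.25, Rap2b, a small GTPase, at 1.11 ± 0.23, Pou2f2, a lymphoid transcription factor, at 1.03 ± 0.23 and Steap2, a metal reductase, at 0.83 ± 0.20. Signed as deposited, the means were -0.79 for Rgcc, -1.44 for Rnf112, -0.32 for Rps6, -0.80 for Selenon, -0.18 for Dgcr8, -0.38 for Csnk1d, 0.62 for Lrrc71, 0.71 for Tsfm, 0.59 for Rap2b, 0.49 for Pou2f2 and 0.39 for Steap2. The paired spots of Lrrc71, Dgcr8 and Rps6 differed by up to 3.44, 3.12 and 2.78 log2 units. Only Steap2 and Csnk1d among these 11 genes had agreeing spots. Hif1a was at 0.80 ± 0.27 and Calcrl at 0.94 ± 0.30, against 1.00 and 1.53 as deposited. Single arrays carried some of these means: leaving out each array in turn moved Calcrl to between 0.16 (without the unreversed array against 1-week control) and 1.72 (without its dye reversal), and Rnf112 to between -0.57 and -2.39 by the same arrays. Hif1a moved to between 0.35 (without the array against 6-week control) and 1.18 (without the dye reversal).

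Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, had positive 6-week medians under both signs, of which the rule's rested on single arrays. With the rule's sign 16 of 22 were positive, with a median of 0.22, a camera adjusted p of 0.0503 and an estimated-correlation adjusted p of 0.934; leaving out each array in turn moved the median to between 0.01 (without the array against 6-week control) and 0.31 (without the dye reversal). As deposited all 22 were positive, with a median of 0.28, a camera adjusted p of 1.41e-05 and an estimated-correlation adjusted p of 0.587, and adjusted over the list alone 0 passed. Dusp1, a phosphatase that ends MAP kinase signalling, was at 0.74 with the rule's sign and 0.95 as deposited, and without the unreversed array against 1-week control at 0.17 and 0.59. Klf4 was at 0.44 with the rule's sign and 0.89 as deposited. Of genes in other lists, Il6, an inflammatory cytokine, stood at 0.65 with the rule's sign and 1.00 as deposited, Edn1, the precursor of the vasoconstrictor endothelin, at 0.51 and 1.27, and Ptgs2, the inducible cyclooxygenase, at 0.38 and 0.78.

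Oxidative phosphorylation genes had a 6-week median of -0.06 with the rule's sign (camera adjusted p 0.579) and -0.24 as deposited, where 39 of 48 were negative with a camera adjusted p of 0.000118 and an estimated-correlation adjusted p of 0.587. Adipocyte markers had a median of -0.14 with the rule's sign (camera adjusted p 0.259) and -0.40 as deposited, with a camera adjusted p of 0.00531 and an estimated-correlation adjusted p of 0.587. Without the array against 6-week control that median was -0.08, with a camera adjusted p of 0.0559. Ucp1, the uncoupling protein of brown fat, was at -1.27 as deposited and -0.26 with the rule's sign, Thrsp, a lipogenic factor, at -0.81 and -0.44, and Cidea, a lipid droplet protein, at -0.61 and -0.07. Fabp4, a fatty acid carrier of adipocytes and capillaries, was at -0.66 as deposited (-0.42 without the array against 6-week control) and -0.35 with the rule's sign, while Adipoq, the hormone adiponectin, was at 0.07 and -0.01. Acsl3, which activates fatty acids, was at -1.07 as deposited and -0.50 with the rule's sign. Of the endothelial markers, Cldn5, a tight junction protein, was at -0.90 as deposited and -0.07 with the rule's sign, and Car4, a capillary carbonic anhydrase, at -0.94 and -0.41. Other endothelial markers were positive. Those with the smallest 6-week p in limma's test with the rule's sign were Tek at 0.29, Pecam1 at 0.38, Sox7 at 0.26 and Flt1 at 0.36, and none passed. Ribosomal protein genes had a 6-week median of 0.00 with the rule's sign and -0.09 as deposited, with 31 positive and 31 negative under the rule. Cyp1a1 was at -0.02 with the rule's sign and -0.06 as deposited, and Cyp1b1 at 0.03 and 0.82.

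**Figure D3:**
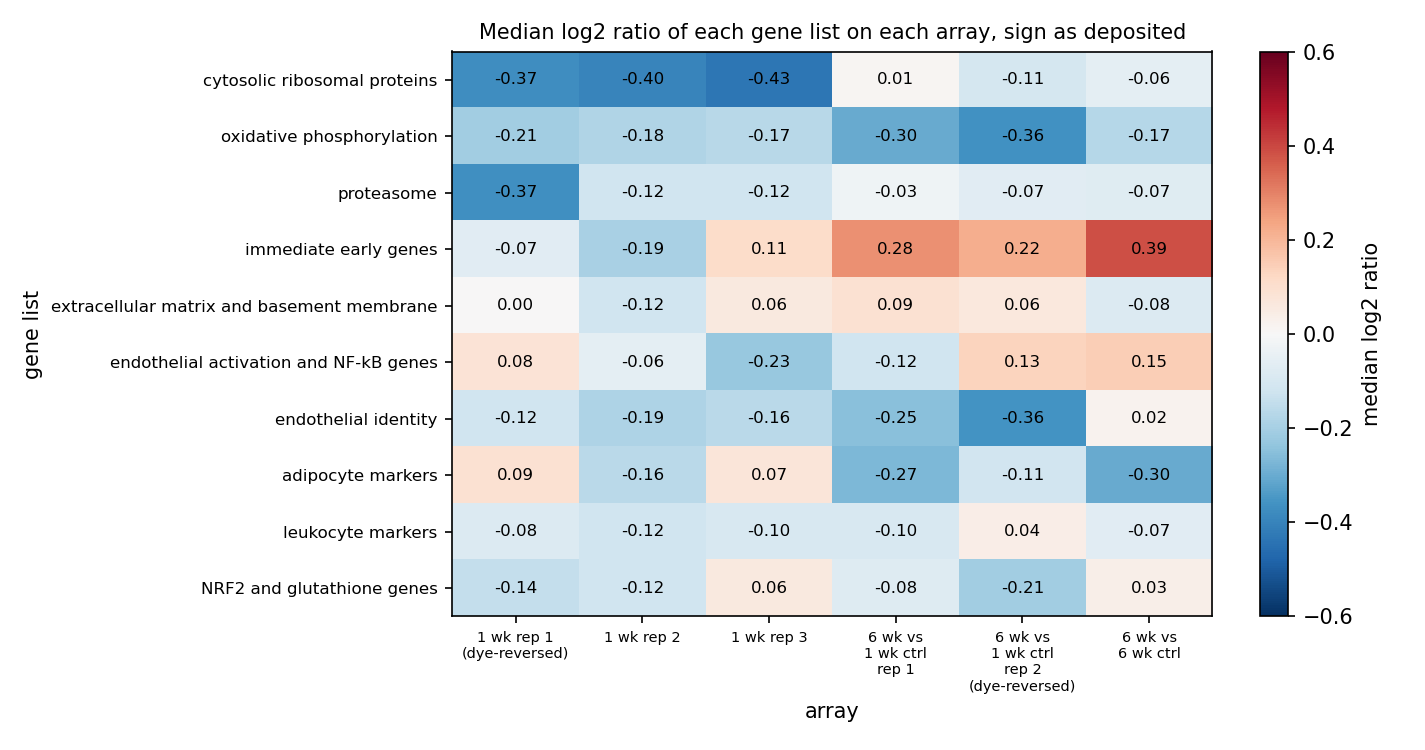
Median log2 ratio (colour and number, sign as deposited) of 10 gene lists (vertical axis) on each of the 6 arrays (horizontal axis). The ribosomal list lies between -0.43 and -0.37 on the 1-week arrays and between -0.11 and 0.01 on the 6-week arrays, and the immediate early list lies between 0.22 and 0.39 on the 6-week arrays.

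The difference between exposure times was tested as 6-week minus 1-week. Except for Plagl1 and Serpina1c, chosen with signs as deposited, the genes named here are among those with the smallest p under the rule's sign. None passed over all tests. Rps18 differed by 2.44 ± 0.25, Rplp2 by 2.19 ± 0.28, Dynll1 by 2.08 ± 0.37, Klf2 by 1.68 ± 0.28 and Jund by 1.13 ± 0.25, with the 6-week values the higher. Gpr160 differed by -1.61 ± 0.29, Hnrnpm by -1.51 ± 0.33, Trp53inp1 by -1.43 ± 0.29, Mfsd8 by -1.36 ± 0.28 and Id3, an inhibitor of differentiation factors, by -1.36 ± 0.30, with the 6-week values the lower. Psmd6 differed by 1.20 ± 0.27, and Col4a2 by 1.73 ± 0.37, which became 1.11 without the 6-week dye reversal and -0.34 with the dye-reversed arrays given the other sign. Signed as deposited, the differences were 2.12 for Rps18, 1.72 for Rplp2, 2.10 for Dynll1, 1.68 for Klf2, 1.08 for Jund, 1.18 for Psmd6, 0.85 for Col4a2, -1.75 for Gpr160, -1.33 for Hnrnpm, -1.42 for Trp53inp1, -1.21 for Mfsd8 and -1.23 for Id3. Some genes differed through their 6-week values instead, each under 1 sign mainly: Plagl1 by 1.60 as deposited and 0.45 with the rule's sign, Serpina1c by 1.60 and 0.51, and Rgcc by -1.54 with the rule's sign, its 6-week mean shrinking from -1.86 to -0.79 as deposited.

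Over all tests limma's count was 0 for this difference, with a smallest adjusted p of 0.957. An unadjusted p under 0.05 was reached by 633 features against 962 by chance, and by 640 to 1104 when leaving out each array in turn (the latter without the array against 6-week control). Robust limma gave 0 and the test without moderation gave 2. Among genes with agreeing spots 1 passed, Rps18, with an adjusted p of 0.0249; signed as deposited, 0 passed and its adjusted p was 0.0682. The ribosomal list had a median difference of 0.43, with 49 positive and 13 negative, a camera adjusted p of 4.18e-08 and an estimated-correlation adjusted p of 0.854; adjusted over the list alone 2 genes passed. Signed as deposited the median difference was 0.39, with a camera adjusted p of 4.65e-07 and an estimated-correlation adjusted p of 0.25. The call was lost with the dye-reversed arrays given the other sign, where the median difference was 0.06 and the adjusted p 0.665. That alternative turns the 1-week dye reversal, so a smaller 1-week median follows from the turn itself. The immediate early list had a median difference of 0.21, with a camera adjusted p of 0.052 and an estimated-correlation adjusted p of 0.934; adjusted over the list alone 1 gene passed. Signed as deposited the median was 0.31, with a camera adjusted p of 0.00023 and an estimated-correlation adjusted p of 0.587. Leaving out each array in turn moved the median of the rule's sign to between 0.05 (without the array against 6-week control) and 0.37 (without the 6-week dye reversal).

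Over both exposure times, some genes had one sign on all 6 arrays as deposited. Cpe, an enzyme that processes peptide hormones, lay between 2.02 and 3.15 on these arrays. Coch, a secreted matrix protein, had a mean of 2.06 ± 0.18 (SE, n = 5 replicates), Calcrl 1.34 ± 0.11, Tsc22d3 1.22 ± 0.12, Clu 1.27 ± 0.13 and Fhl1 1.22 ± 0.12. The SEs in this paragraph come from the fit of genes with agreeing spots. Tmem88, a membrane regulator of Wnt signalling, was at -1.06 ± 0.14, Cldn5 at -0.79 ± 0.13 and Ly6e, a surface protein of endothelial and immune cells, at -0.68 ± 0.12. With the rule's sign the means were 1.86 for Cpe, 1.44 for Coch, 1.04 for Calcrl, 0.89 for Tsc22d3, 1.00 for Clu, 0.92 for Fhl1, -0.70 for Tmem88, -0.38 for Cldn5 and -0.44 for Ly6e. With every array over 0.58 in size there were 26 genes, and 20 of them had one sign on all 6 arrays, 16 positive and 4 negative. The arrays are not independent, since 2 form a dye swap and others may share RNA, so no frequency without a smoke effect is given. Both dye-reversed arrays were opposite to the others in 3 genes, and only the 6-week dye reversal was opposite in 0. With every array over 0.3 in size there were 253 genes, and these 3 patterns held 91, 29 and 3 of them. With no limit on size they held 764, 719 and 483 of 10685 genes, so one sign on all arrays was then hardly more frequent than opposite signs on both dye-reversed arrays.

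With the rule's sign limma's count for the mean of both times was 0, with a smallest adjusted p of 0.836. An unadjusted p under 0.05 was reached by 984 features against 962 by chance, with 785 to 1262 when leaving out each array in turn, robust limma gave 0, and the test without moderation gave 2. Genes of one sign on every array included Rab27b, a GTPase of secretory vesicles, at 0.81 ± 0.14 (SE), Tra2b, a splicing factor, at 0.62 ± 0.18, Selenon at -0.84 ± 0.13 and Anp32a, a nuclear phosphoprotein, at -0.66 ± 0.13. Signed as deposited these were 0.77 for Rab27b, 0.58 for Tra2b, -0.77 for Selenon and -0.62 for Anp32a. Among genes with agreeing spots 0 passed with the rule's sign and 106 passed as deposited, 68 positive and 38 negative. They included Coch with an adjusted p of 0.00229, Calcrl with 0.00229, Fhl1 with 0.00346, Tsc22d3 with 0.00346, Clu with 0.00361, Tmem88 with 0.0122, Cldn5 with 0.0223 and Ly6e with 0.0353. Cpe was not in that test because its spots differed by up to 1.06.

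The 6-week arrays against 1-week and against 6-week control were set side by side as values, with no test, because each is 1 replicate. Across 11138 named genes, which are not independent replicates, they correlated at r = -0.00516 (rho = -0.0265) with the rule's sign and at r = 0.117 (rho = 0.0709) as deposited. Whether these arrays shared the RNA of 6-week smoke was not stated. A difference over 1 log2 unit was seen for 1036 genes with the rule's sign and 818 as deposited. Postn, a matrix protein of fibroblasts, was at 3.25 against 6-week control and at a mean of 1.24 as deposited over the arrays against 1-week control. With the rule's sign, the Postn value against 6-week control exceeded its mean against 1-week control by 3.51. That mean was therefore negative under the rule, so its direction depended on the sign of the dye-reversed array. Ceacam2, a cell adhesion molecule, was at 2.82 against 6-week control and, as deposited, at -1.89 and 0.04 against 1-week control. Chil3, a macrophage chitinase-like protein, was at -3.96 against 6-week control and, as deposited, at -0.16 and -0.84 against 1-week control. Its spots differed by up to 6.40. For Ceacam2 and Chil3 too, the rule gave the value of the dye-reversed array the opposite sign.

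With the rule's sign, the remaining lists had medians between -0.16 and 0.20 with no camera call at either exposure time. The 1-week median is given first and then the 6-week median. Endothelial identity genes, 22 measured, had medians of -0.10 and 0.05, and the angiogenesis and Notch list -0.05 and 0.03. Vascular tone and nitric oxide genes had -0.06 and -0.05, coagulation and fibrinolysis genes -0.08 and 0.00, and extracellular matrix genes -0.02 and -0.01. The interferon-stimulated genes had -0.10 and 0.05, the endothelial activation list -0.02 at 6 weeks, the immediate early list -0.16 at 1 week and the proteasome 0.09 at 6 weeks. Heat shock proteins had -0.16 and -0.02, the unfolded protein response -0.02 and -0.08, NRF2 and glutathione genes -0.04 at 6 weeks, the other antioxidant genes -0.01 at 6 weeks and the aryl hydrocarbon receptor targets -0.07 at 6 weeks. Proliferation genes had -0.12 and -0.04, p53 and apoptosis genes 0.12 and 0.02, glycolysis -0.09 and -0.16, sterol and fatty acid metabolism 0.05 and -0.04, clock genes 0.01 and 0.02, and glucocorticoid-induced genes 0.20 and 0.09. Among genes with agreeing spots and signed as deposited, camera called 3 of these lists at 6 weeks: vascular tone (median 0.17, adjusted p 0.0211), endothelial identity (-0.29, adjusted p 0.0322) and glycolysis (-0.18, adjusted p 0.0333), with estimated-correlation adjusted p of 0.586, 0.813 and 0.615.

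Of the cell type markers, leukocyte markers had medians of -0.10 and -0.06, erythroid and platelet markers -0.09 and -0.05, smooth muscle and pericyte markers 0.03 and 0.01, and fibroblast markers -0.12 and -0.04. Lung and airway epithelium markers had -0.09 and -0.02, cardiac and skeletal muscle markers -0.13 and -0.02, liver and kidney markers -0.05 and 0.14, neural and melanocyte markers -0.09 and -0.13, and adipocyte markers -0.01 at 1 week. The 4 measured sex-linked genes, too few for a test, had 0.09 and 0.14. Median, mean and camera direction had one sign in 69 of the 93 tests and differed in 24, none of which passed.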

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

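All tests of explanations given here were chosen only after the results were seen, and the signs as deposited and the agreeing-spot genes are alternatives added after seeing the data.

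The response of some gene groups differed between 1 and 6 weeks by the test of the difference. The ribosomal list did so with the rule's sign (median difference 0.43, camera adjusted p 4.18e-08) and as deposited (0.39). As deposited, differences also passed camera for the immediate early genes (0.31, adjusted p 0.000229), the endothelial activation and NF-kB genes (0.22, adjusted p 0.0114), the extracellular matrix genes (0.26, adjusted p 0.0313) and the adipocyte markers (-0.39, adjusted p 0.0339). None of these held with an estimated correlation, where the adjusted p lay at 0.854 for the ribosomal list with the rule's sign, at 0.25 for it as deposited and at 0.587 for the others. The ribosomal call was also lost with the dye-reversed arrays given the other sign (median difference 0.06, adjusted p 0.665). Every 1-week array had a negative ribosomal median, so turning the 1-week dye reversal makes the 1-week median smaller by itself. Rps18 differed by 2.43 among genes with agreeing spots, with limma's adjusted p of 0.0249 under the rule's sign. Signed as deposited, limma's adjusted p for it was 0.0682, and it did not pass. No group of samples was large enough for a check of single arrays that lie far from the others.

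The ribosomal genes had a negative median on all 3 of the 1-week arrays, including the dye-reversed one, and a median near 0 at 6 weeks. A fixed dye effect on these probes would show at both times, yet their median over the unreversed 6-week arrays was -0.0493 (95% bootstrap interval over genes -0.137 to 0.0569) against -0.411 over the unreversed 1-week arrays. A bias of abundant transcripts would lower other abundant transcripts as much, yet 27 of them had a 1-week median of -0.0547 (interval -0.206 to 0.277), with Tpt1 at -1.02 and Eef1a1 at 0.41. Fewer leukocytes among the sorted cells would lower leukocyte markers. The 36 markers had a median of -0.103 (interval -0.214 to -0.00263), above the ribosomal -0.392 but with an interval below 0, with Lyz2 at -0.58 and Cd74 at -0.23. Signal over background was not assessed, and markers near background can lie near 0 whatever the share of leukocytes. This comparison therefore cannot decide whether leukocytes were fewer. An effect of exposure time, the unstated control of the 1-week arrays and a difference in RNA handling stay open as untested candidate explanations, and the estimated-correlation adjusted p of 0.854 leaves open shared variation of these genes between arrays.

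The 2 dye-reversed arrays correlated with each other at r = 0.272 across named genes, more than with the unreversed arrays of their own comparisons. Noise of spots that do not repeat would weaken this among genes with agreeing spots, yet the correlation there was 0.430. Other correlated pairs rose too, as the unreversed 1-week arrays did from 0.148 to 0.389, so this argues only against such noise as the source and says nothing specific to the dye-reversed pair. If a dye-reversed ratio had been deposited unturned, genes picked on the unreversed arrays of one exposure time, and within 0.5 of 0 at the other, would lie on the opposite side on it. Yet 75 of 87 such 1-week genes kept their side on the 1-week dye reversal (median 0.58, interval 0.484 to 0.782), and 31 of 48 such 6-week genes kept theirs on the 6-week dye reversal (median 0.252, interval 0.00677 to 0.521). The second interval barely excludes 0 and takes genes as independent, so this test alone is a weak argument against an unturned 6-week ratio. It goes against the sign the rule gave that array, and sign patterns as deposited lean the same way. With every array over 0.3 in size, 91 genes had the same sign on all 6 arrays, and 3 had only the 6-week dye reversal opposite. With no limit on size these patterns held 764 and 483 genes. The arrays are not independent, so these counts were not tested. Across all named genes, the 6-week array and its dye reversal still correlated at r = -0.0302 as deposited.

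A gene-specific dye effect shared by arrays of one orientation may remain. Unreversed 1-week and unreversed 6-week arrays correlated at a mean r of 0.127 (0.0916 to 0.178), and unreversed with reversed arrays of the other time at -0.00754 (-0.0482 to 0.0810). Arrays hybridised together would give the same values, and the labels name no batches, so a dye effect and a batch are not separated by this test. The array against 6-week control showed little difference by orientation. It correlated with the reversed arrays at r = 0.0810 and r = 0.0892, and with the unreversed ones between r = 0.0742 and r = 0.141. No biological explanation was tested, since the design gives none for the dye orientation.

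The adipocyte markers' negative 6-week median as deposited, -0.402, might come from fewer adipocytes among the sorted cells. This could not be settled: the interval over 12 markers ran from -0.643 to 0.0133, Adipoq was at 0.0659 and Retn at 0.30, markers that adipocytes express highly, while Ucp1 was at -1.27. Fabp4 is also expressed by endothelial cells, and a sort for endothelial cells would remove most adipocytes. The 6-week smoke animals on 2 of the 3 arrays were compared with 1-week controls, so age also stays open; the median was -0.30 on the array against 6-week control, and -0.08 without that array (camera adjusted p 0.0559).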

How the results depend on the processing

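The alternatives with signs as deposited, with the 4 unreversed arrays and with agreeing-spot genes were chosen after seeing the data. Of 106 gene values followed over the alternatives, 102 kept their direction under each that gave a value. Many of these genes were named because they had the same sign on every array of a contrast. Leaving out an array could not reverse those, so the count of 102 is partly fixed by this choice. Other gene values in the text were not followed, among them Adipoq, Retn, Cyp1a1, Postn, Ceacam2 and Chil3; Adipoq was at 0.07 at 6 weeks as deposited and at -0.01 with the rule's sign. With the dye-reversed arrays given the other sign, the 1-week values of Ccl2 (0.0962), Gpx1 (0.00834) and Cyp1b1 (-0.277), the 1-week proteasome median (0.0491) and the Col4a2 difference (-0.335) reversed. Other 1-week values kept their sign there but shrank, as Rps18 did from -2.25 to -0.67, Dynll1 from -2.01 to -0.34, Klf2 from -1.34 to -0.24, Rps16 from -1.58 to -0.16, Btg1 from 1.27 to 0.25 and Serinc1 from 1.85 to 0.61, since the alternative turns 1 of the 3 arrays in each mean.

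The count of passing genes was 0 in all 4 contrasts under every alternative fixed beforehand except the following. Testing only the 11138 named genes, all with several spots, gave 2 genes at 1 week, Rps18 and Rplp2, both negative; fewer features were tested. The test without variance moderation gave 3 at 6 weeks, 2 for the difference and 2 for both times; the cause was not tested. Among agreeing-spot genes the counts were 78 at 1 week and 1 for the difference. With signs as deposited too, they were 102 at 1 week, 12 at 6 weeks and 106 for both times. Fewer genes were tested, but the share with an unadjusted p under 0.05 in limma's test rose as well. At 1 week it was 6.31% over all features and 13.3% among agreeing-spot genes, and 6.65% and 14.1% as deposited. A smaller number of tests alone does not change this share, so it does not account for the whole rise. What else entered the rise was not tested. Leaving out each array in turn gave 0 to 0 in every contrast. The 3 arrays of 1 week allow 4 splits by sign, too few for a share under 0.05; the real one gave 78 genes and the highest other gave 0.

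Gene lists called by camera numbered 3 (1 up, 2 down). They numbered 0 with an estimated correlation, 0 with fry (2 with signs as deposited and 2 with agreeing spots too), 6 after quantile normalization (3 up, 3 down), 8 with every probe on its own (4 up, 4 down), 5 without unnamed features, 6 at a threshold of 0.10, 11 with signs as deposited, 6 on the 4 unreversed arrays, 6 with agreeing spots and 14 with both, and 2 to 9 when leaving out each array in turn (6 without 1-week replicate 3 and 9 without the 6-week dye reversal). Beyond the change in genes, sign or correlation each makes, the cause was not tested. The ribosomal 1-week median ranged from -0.42 to -0.14 over alternatives and from -0.41 to -0.35 when leaving out each array. With the dye-reversed arrays given the other sign, the ribosomal call was lost at 1 week (adjusted p 0.189) and for the difference (median 0.06, adjusted p 0.665). The oxidative phosphorylation 1-week call was lost with a dye term (adjusted p 0.222), with 6 separate replicates (0.102), with the 1-week dye reversal averaged with another array (0.0978 and 0.0975), with the dye-reversed arrays' other sign (0.989), on the 4 unreversed arrays (0.181), without 1-week replicate 1 (0.265) and without the 6-week array against 1-week control (0.0729). The as-deposited adipocyte call was lost without the array against 6-week control (median -0.08, adjusted p 0.0559).

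The correlation between 6-week arrays of both control ages was -0.00516 and became 0.117 as deposited, since the turn changes the mean it enters. Among agreeing-spot genes it was -0.0205 with the rule's sign and 0.217 as deposited; the cause of the step from 0.117 to 0.217 with the spot filter was not tested. The alternative on missing values gave no value because none were missing. No paired analysis was possible because the labels give no replicate numbers. Signal over background was not used here, so its limit on dim genes is unknown.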

Other observations

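The 5550 features after the last named one behaved unlike the named ones, and these values were looked up after seeing the data. Their paired values correlated between r = -0.00248 and r = 0.0301 on the 6 arrays, against 0.212 to 0.412 for named features. From 24.3% to 49.2% of them stood at a fold of exactly 1, against 2.20% to 5.11% of named features. The share of named genes more than 1 log2 unit from 0 ranged from 3.86% on the array against 6-week control to 8.60% on 1-week replicate 3.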
